A study of Mus musculus with 12 samples.

How the data were processed

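The intensity values were the mean bead signals of 45281 probes on each of 12 Illumina mouse whole-genome arrays, and per the file headers GenomeStudio's Gene Expression module, version 1.9.0, exported them with no normalization, in 1 report per BeadChip. Background had not been subtracted from the deposited signals, all of which were positive. The detection p-values were computed by the authors' scanner software per array against the array's background probes before the reports were deposited. The number of beads behind each signal was also deposited, with a median of 35 to 41 per probe. A separate matrix of intensities was normalized between arrays by the authors by a method not given in the sources used here. Its column medians were 170.18 to 172.05, and each column had a Spearman correlation of 1 with its own array and at most 0.914 with another. That matrix was used only as an alternative.

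Samples were assigned to groups from their titles. One line of the series design text gives 0.1 µM for CDDO-Im where the titles and the treatment protocol give it for CDDO-Me, and the titles were followed. RNA was prepared with RNeasy columns and labelled with biotin, per the labels.

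The choices that follow were made before the data were examined, apart from those said to be later. Signals were corrected for background with limma's normexp method, which estimated the background from the detection p-values, with an offset of 16, then quantile normalized over the 12 arrays and put on the log2 scale. Probes with a detection p under 0.05 in at least 3 arrays were kept, 19211 in all. Gene names were updated by Entrez number for 29586 probes and by transcript accession for 2759, and 12936 kept the name on the array; 6861 symbols changed. For each gene the kept probe with the highest mean log2 signal was used, giving 13280 genes of 30561 on the array, 9221 of them with 1 kept probe and 4059 with several. Of the called named genes with several kept probes, the probes had the same sign for 14 of 15 with CDDO-Im, 15 of 17 with CDDO-Me and 11 of 11 with DMF. Close paralogs such as Gsta1 and Gsta2 may share probes.

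Differences were tested with limma (version 3.58.1 in R 4.3.3) in one fit of all 12 arrays with group and chip as terms, 7 residual and 2.87 prior degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The chip term itself called 0 genes with 12 arrays, and 33 with 10. Gene lists were tested with camera at a preset correlation of 0.01 between genes and again with a correlation estimated from the data, adjusted over 174 tests, which were 28 fixed lists and the joined NRF2 list in 6 comparisons. Each list's value is the median log2 difference of its tested members. Members were also adjusted over the list alone.

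The 28 lists were written down beforehand. 6 held NRF2 targets and regulators: glutathione synthesis and use, quinone and aldehyde metabolism, thioredoxins, pentose phosphate and NADPH supply, heme and iron, and pathway regulators. The others held heat shock, ATF4, ER chaperone, proteasome, NF-kB, interferon, STAT3, immediate early, S and G2/M phase, p53, cholesterol, fatty acid, TGF-beta and matrix, hypoxia and glycolysis, aryl hydrocarbon receptor, metallothionein, apoptosis and histone genes, and markers of lung epithelium, fibroblasts, leukocytes and endothelium.

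Named genes followed a rule. A gene was eligible if it was called, had the same sign within each chip and had a symbol that was not a clone or locus type. With a few genes left out, the text names the 10 largest rises and the 10 largest falls per compound against DMSO, up to 4 called members of each list by size, or the member with the smallest p where none was called, and 8 genes in any case (Nqo1, Hmox1, Gclc, Gclm, Txnrd1, Srxn1, Slc7a11 and G6pdx). Between compounds it names the 6 largest eligible differences each way, or the 5 smallest p-values where none was called. A gene undetected in one group is given as a bound, at least so many fold.

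Overlaps were counted for genes called in the same direction and set against the product of the counts over the genes tested, and against 50 simulated sets of unchanged groups that shared controls (seed 20).

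The tests were checked on simulated data of 13280 genes. With 12 arrays, 4-fold changes were found for 59.1% to 78.8% of genes, 2-fold changes for 13.4% to 22.4% and 1.5-fold changes for 0%, with 0 unchanged genes called. With 10 arrays the ranges were 100% for 4-fold, 89.6% to 97% for 2-fold and 43.3% to 80.6% for 1.5-fold, with 2 to 9 unchanged genes called. The 10-array fit, without DMSO replicate 1 and CDDO-Im replicate 2, was added after seeing the data, as was its repeat with background correction, normalization, filter and probe choice made again on those arrays.

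Alternatives written down beforehand covered no background correction, an offset of 50, cyclic loess, median scaling, a stricter detection filter (0.01), no filter, the mean of a gene's probes, every probe by itself, the matrix values, no chip term, the chip as a random block, each chip alone, the replicate number as a block, an intensity trend with robust variances, array quality weights (estimated gene by gene, as the REML estimate did not converge), the 2 compared groups alone, a fold minimum of 1.5, the estimated correlation, a stricter overlap (0.01) and each array left out.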

Results

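RNA of VC1 cells, a mouse lung adenocarcinoma line from the A/J strain, was measured on 12 Illumina expression arrays after 6 h of treatment. The cells received DMSO alone, 0.05 µM CDDO-Im, 0.1 µM CDDO-Me or 15 µM DMF, with 3 arrays per group. CDDO-Im and CDDO-Me are the imidazolide and the methyl ester of one synthetic oleanane triterpenoid, and DMF is the dimethyl ester of fumaric acid. The series title names all 3 as activators of NRF2, the transcription factor that KEAP1 holds at a low level until electrophiles modify KEAP1. The design text of the series writes CDDO-Im beside 0.1 µM, where the sample titles and the treatment protocol write CDDO-Me, and the titles were followed. The labels do not say whether replicates were separate cultures, so the p-values measure the spread among these samples, which may be technical. The 12 arrays came on 2 BeadChips that each held all 4 groups, and 3 arrays per group limit the precision of every value.

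Hmox1 and Slc7a11 were higher on each treated array than on any DMSO array, while 2 arrays stood apart from the rest. DMSO replicate 1 and CDDO-Im replicate 2 were both on chip 1. The 10 other arrays correlated at 0.988 or more among themselves, and these 2 had median correlations across the genes tested of 0.916 and 0.936 with them. Their mean raw intensities were 439.6 and 457, against 552 to 684 on the other arrays, and 38.1% and 32.7% of their probes were detected, against 38.3% to 41.3%. ER chaperone genes lay below the other arrays of the same group by a median log2 difference of -0.56 on DMSO replicate 1 and -0.57 on CDDO-Im replicate 2 (17 genes), and fatty acid synthesis genes by -0.70 and -0.67 (11 genes). TGF-beta and matrix genes lay above them by 0.39 and 0.38 (20 genes). Other lists differed between the 2 arrays, such as heat shock genes (-0.41 and -0.03, 19 genes) and endothelial markers (0.12 and 0.96, 6 genes). Across genes the deviations of the 2 arrays correlated at 0.295. The 72 tested NRF2 pathway genes differed by medians of -0.06 and 0.03, with 4 over 1 and 10 under -1 on DMSO replicate 1, and 2 and 6 on CDDO-Im replicate 2. With both arrays in the fit the median standard error of a log2 difference was 0.242 to 0.25, and with the other 10 arrays alone, a choice made after seeing the data, it was 0.0855 to 0.105. Each lead count from the 12 arrays is therefore given beside that from the 10.

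**Figure D1:**
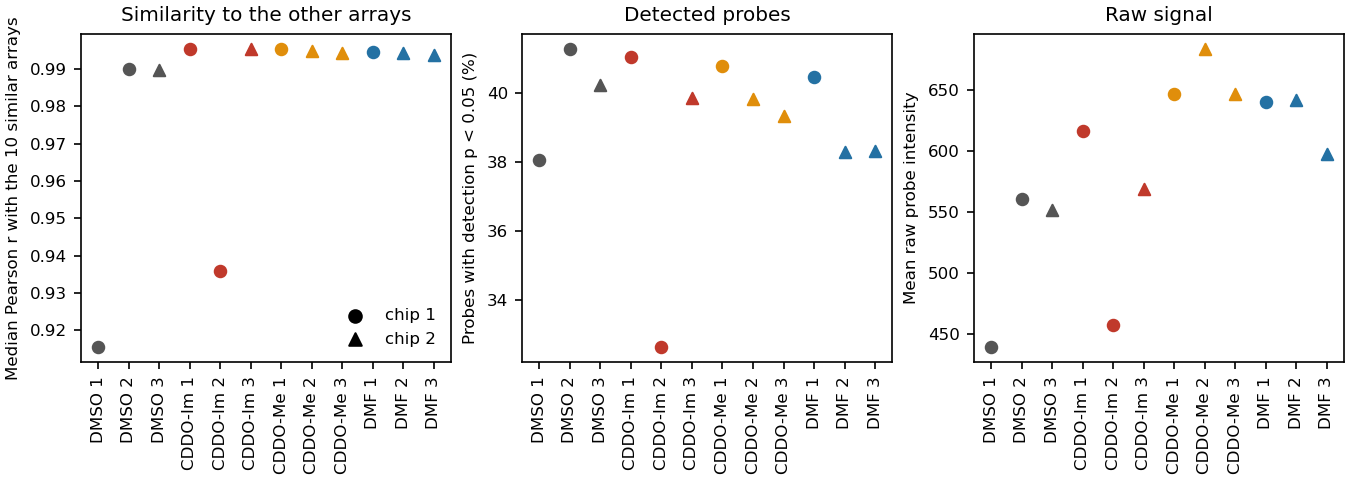
For each of the 12 arrays, the first panel gives the median Pearson r across the genes tested with the 10 similar arrays. The others give the percentage of probes with a detection p under 0.05 and the mean raw intensity. Circles are chip 1 and triangles chip 2, coloured by group. DMSO replicate 1 (r 0.916) and CDDO-Im replicate 2 (r 0.936) lie apart from the others (r 0.990 to 0.996).

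Hmox1 had the largest rise with CDDO-Im among the genes eligible to be named, and Slc7a11, Cbr3 and Gsta3 were among the 10 largest. The log2 rise against DMSO was 4.41 ± 0.38 for Hmox1, the heme oxygenase that opens the heme ring (limma adjusted p = 0.0003). In the 10 arrays it was 5.13, as DMSO replicate 1 was the brightest of its group and CDDO-Im replicate 2 the dimmest of its own. Slc7a11, the cystine carrier that feeds glutathione synthesis, rose by 3.83 ± 0.17 (limma adjusted p = 5.38e-06). Values after ± are standard errors of the log2 difference from limma, with 3 arrays per group. Cbr3, a carbonyl reductase, rose by 3.48 ± 0.31 and Gsta3, a glutathione transferase, by 3.54 ± 0.17, which was at least 9.55-fold because no DMSO array detected it. Such a bound divides the bright group's mean by the dim group's mean of, per array, the higher of the lowest detected-probe signal and the probe's own. The other largest rises were Dppa5a (4.14), Ampd3 (3.92), Calr3 (3.59), Abcb4 (3.58), Trim54 (3.38, at least 7.37-fold with the brightest array, CDDO-Im replicate 2, and 2.76 in the 10 arrays) and Mest (3.36). Among the lower genes, the kinase Map2k6 fell by 2.18 ± 0.46 (adjusted p = 0.0469) and the matrix protein gene Thbs1 by 1.81 ± 0.38 (adjusted p = 0.0438). With only the 10 arrays Map2k6 was 1.27 lower, Thbs1 1.17 and Dynap 1.14, all smaller than the 1.67 of Sox9 there. The tight junction gene Cldn2 fell by 1.57 ± 0.14 (adjusted p = 0.000431) and the transcription factor gene Sox9 by 1.46 ± 0.18 (adjusted p = 0.00312). The other largest falls were Ripply1 (-1.91), Dynap (-1.80), Serpinb2 (-1.66), Creb5 (-1.56), Sgsm1 (-1.53) and Grem1 (-1.47).

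Of 13280 genes tested with limma, 188 were higher and 52 lower with CDDO-Im than with DMSO, 240 in all, each with the same sign within both chips. The calls rest on both chips, so that agreement in sign is no separate test, here or for the other comparisons. In the 10 arrays 764 were higher and 664 lower. Within chip 2, which held 1 array of each of these groups, 292 genes were called with a spread taken from the other groups, so that count does not test replication. Within chip 1, with 2 arrays of each, limma called 0, with 212 at an unadjusted p under 0.05. Both outlying arrays were on chip 1. Fitted with only the 2 groups compared, 3 genes were called, so nearly every call depends on the fit of all 4 groups together. The count was 383 without DMSO replicate 1, 121 without DMSO replicate 3 and 101 without CDDO-Im replicate 3.

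Each group of NRF2 target genes was higher with CDDO-Im than with DMSO. Of the 72 tested members of the 6 lists joined, 35 were called higher and 0 lower, 44 and 0 adjusted over the list alone, with a median log2 difference of 0.825 (0.845 within chip 1, 0.823 within chip 2). The shift had an adjusted p of 8.43e-33 in camera and of 0.000191 with an estimated correlation. In the 10 arrays the median was 0.844 and 53 members were called higher. The glutathione group (20 tested, median 1.01, 11 called, 15 adjusted over the list alone) held Gclc at 2.77 ± 0.19 (adjusted p = 5.59e-05) and Gclm at 2.29 ± 0.20 (adjusted p = 0.0003), the subunits of the enzyme that limits glutathione synthesis, beside Gsta2 at 2.86 and Gsta1 at 2.84. Probes of Gsta1 and Gsta2, close paralogs, may bind both transcripts. The quinone and aldehyde group (20 tested, median 1.17, 12 called, 14 adjusted over the list alone) held Nqo1, a quinone reductase, at 1.59 ± 0.23 (adjusted p = 0.00651), Aldh1a1 at 2.01, Aldh1a7 at 1.88 and Aldh3a1 at 1.70. In the heme and iron group (9 tested, median 1.27, 5 called, 5 adjusted over the list alone) the iron exporter Slc40a1 rose by 2.99, the biliverdin reductase Blvrb by 2.54 and Abcb6 by 1.29. Of 8 thioredoxin genes (median 0.66, 2 called, 2 adjusted over the list alone), Srxn1 rose by 2.62 ± 0.18 (adjusted p = 4.45e-05) and Txnrd1 by 2.51 ± 0.43 (adjusted p = 0.0168; 1.75 in the 10 arrays). The NADPH supply group (7 tested, median 0.637, 2 called, 4 adjusted over the list alone) held Taldo1 at 0.91 and Pgd at 0.81, while G6pdx differed by 0.29 ± 0.20 (adjusted p = 0.516; 0.61 and adjusted p = 0.00598 in the 10 arrays). Of 8 pathway regulators (median 0.523, 3 called, 4 adjusted over the list alone), Bach1 rose by 2.01, the autophagy adaptor Sqstm1 by 1.22 and Mafg by 1.20. The adjusted p for the shift was 9.1e-19 for the glutathione group (0.000515 with an estimated correlation), 2.84e-15 for quinones (0.000813), 2.11e-06 for heme and iron (0.0152) and 0.000302 for NADPH supply (0.0308). The thioredoxin shift (adjusted p = 0.000262) was lost, with adjusted p = 0.0769 with an estimated correlation, and so was that of the regulators (adjusted p = 0.00155), with adjusted p = 0.0507 with an estimated correlation; these values were 0.0413 and 0.0432 in the 10 arrays. The thioredoxin genes lay at a median of -0.51 on DMSO replicate 1, and their median was 0.209 in the 10 arrays.

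**Figure D2:**
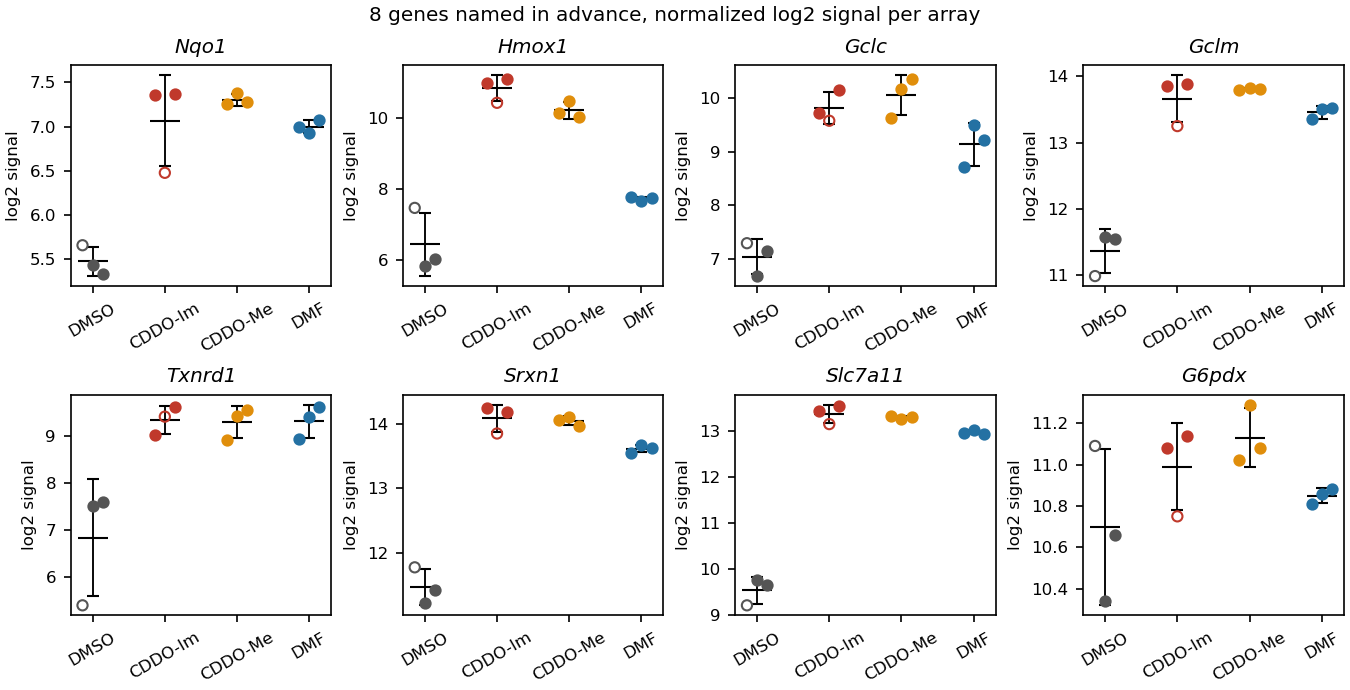
Log2 signal of Nqo1, Hmox1, Gclc, Gclm, Txnrd1, Srxn1, Slc7a11 and G6pdx on each array (circles; open for DMSO replicate 1 and CDDO-Im replicate 2), with the group mean and its SD (bars, 3 arrays per group). Mean Hmox1 was 6.44 with DMSO, 10.8 with CDDO-Im, 10.2 with CDDO-Me and 7.73 with DMF.

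CDDO-Me raised much the same genes at 0.1 µM. Ampd3, an AMP deaminase, rose by 4.06 ± 0.50 (adjusted p = 0.00324), Hmox1 by 3.80 ± 0.40 (adjusted p = 0.00112), Slc7a11 by 3.72 ± 0.17 (adjusted p = 7.54e-06) and Cbr3 by 3.44 ± 0.32 (adjusted p = 0.000496). Gsta3 rose by 3.54 ± 0.17, at least 9.52-fold, and the iron exporter gene Slc40a1 by 3.18 ± 0.38 (adjusted p = 0.00254). The remaining largest rises were Dppa5a (3.88), Calr3 (3.62), Mest (3.32) and Abcb4 (3.23). In the 10 arrays Ampd3 rose by 3.49, less than Hmox1 (4.287), Dppa5a (3.861) and Slc7a11 (3.595). Padi1, a peptidylarginine deiminase, fell by 2.01 ± 0.36 (adjusted p = 0.0259), Rasl11b by 1.87 ± 0.17 (adjusted p = 0.00048), Mgat3 by 1.83 ± 0.28 (adjusted p = 0.012) and Sox9 by 1.74 ± 0.19 (adjusted p = 0.00156). Cldn2 fell by 1.71 ± 0.15 (adjusted p = 0.000336). The other largest falls were Tmem86a (-1.91), Ripply1 (-1.73), Gp49a (-1.65), Fcgr3 (-1.58) and the water channel gene Aqp8 (-1.58).

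In limma 136 genes were higher and 53 lower with CDDO-Me than with DMSO, 189 of 13280 and each with the same sign within both chips. The 10 arrays gave 737 higher and 736 lower. Within chip 2, with 2 CDDO-Me arrays and 1 of DMSO, 403 genes were called, and within chip 1, with 1 CDDO-Me array and 2 of DMSO, limma called 0, with 87 at an unadjusted p under 0.05. A group of 1 array has no spread of its own, so neither count tests replication. With only the 2 groups compared 27 genes were called. The count rose to 327 without CDDO-Im replicate 2 and 301 without DMSO replicate 1. It was 42, 86 and 82 without CDDO-Me replicates 1, 2 and 3, 114, 112 and 115 without DMF replicates 1, 2 and 3, and 64 without DMSO replicate 3.

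NRF2 target genes were higher with CDDO-Me than with DMSO in each group. The 72 joined members had a median log2 difference of 0.863 (0.974 within chip 1, 0.797 within chip 2), with 32 called higher and 0 lower, 44 and 0 adjusted over the list alone, and 52 higher in the 10 arrays (median 0.834). Their shift had an adjusted p of 6.32e-42, and 0.000191 with an estimated correlation. Gclc rose by 2.85 ± 0.20 (adjusted p = 6.87e-05), Gclm by 2.37 ± 0.21 (adjusted p = 0.000333) and Gsta1 by 2.81 among 20 glutathione genes (median 1.09, 11 called, 16 adjusted over the list alone). Nqo1 rose by 1.80 ± 0.24 (adjusted p = 0.00493), Aldh1a1 by 2.01 and Aldh1a7 by 1.83 among 20 quinone and aldehyde genes (median 1.09, 10 called, 15 adjusted over the list alone). Of 9 heme and iron genes (median 1.12, 5 called, 5 adjusted over the list alone), Blvrb rose by 2.57 and Abcb6 by 1.21. The thioredoxin group (8 tested, median 0.673, 2 called, 3 adjusted over the list alone) held Srxn1 at 2.57 ± 0.18 (adjusted p = 6.87e-05) and Txnrd1 at 2.24 ± 0.45 (adjusted p = 0.0409). Of 7 NADPH supply genes (median 0.778, 1 called, 3 adjusted over the list alone), Pgd rose by 0.83, and G6pdx differed by 0.40 ± 0.20 (adjusted p = 0.709; 0.60 and adjusted p = 0.00391 in the 10 arrays). Bach1 rose by 2.09, Sqstm1 by 1.35 and Mafg by 1.25 among 8 regulators (median 0.371, 3 called, 3 adjusted over the list alone). The shifts had adjusted p-values of 4.94e-24 for glutathione (0.000379 with an estimated correlation), 2.63e-21 for quinones (0.00046), 7.85e-08 for heme and iron (0.00993) and 2.97e-05 for NADPH supply (0.0191). That of the thioredoxin group (adjusted p = 3.89e-05) was lost at adjusted p = 0.0574 with an estimated correlation, and that of the regulators (adjusted p = 0.0034) at adjusted p = 0.0574 with an estimated correlation; these values were 0.0407 and 0.0688 in the 10 arrays. The thioredoxin median was 0.233 in the 10 arrays.

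DMF at 15 µM raised fewer genes past the threshold, with Ampd3 and Slc7a11 highest in the 12 arrays. In the 10 arrays Slc7a11 rose by 3.265, Dppa5a by 3.027 and Ampd3 by 2.899. Slc7a11 rose by 3.39 ± 0.17 (adjusted p = 2.3e-05), Ampd3 by 3.47 ± 0.50 (adjusted p = 0.0176), Cbr3 by 3.09 ± 0.32 (adjusted p = 0.00174) and Gsta3 by 2.61 ± 0.17, at least 4.99-fold. Egr1, an immediate early transcription factor, rose by 2.66 ± 0.38 (adjusted p = 0.0165) and the matrix protease gene Mmp10 by 2.44 ± 0.16 (adjusted p = 0.00011). Hmox1 differed by 1.31 ± 0.40 and missed the threshold (adjusted p = 0.44), though in the 10 arrays it was 1.79 higher with adjusted p = 0.000153. Dppa5a (3.05), Gsta2 (2.69), Gsta1 (2.65) and Mest (2.41) were the other largest rises. The 3 genes called lower were Palmd (-1.53 ± 0.22, adjusted p = 0.0181), the activin subunit gene Inhba (-0.91 ± 0.15, adjusted p = 0.0343) and the chemokine gene Cxcl12 (-0.89 ± 0.15, adjusted p = 0.0391).

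With DMF 43 genes were higher and 3 lower than with DMSO, 46 of 13280 in limma and each with the same sign within both chips. Over the 10 arrays 552 were higher and 566 lower, so the share called higher was 93.5% with 12 arrays and 49.4% with 10. Within chip 2, with 2 DMF arrays and 1 of DMSO, 147 genes were called, and within chip 1, with 1 DMF array and 2 of DMSO, limma called 0, with 43 at an unadjusted p under 0.05. Here too 1 group had no spread of its own. With only the 2 groups compared 1 gene was called. The count was 121 without CDDO-Im replicate 2 and 108 without DMSO replicate 1. It was 28 without CDDO-Me replicate 1, 24 without DMSO replicate 3, and 23, 24 and 29 without DMF replicates 1, 2 and 3.

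The joined NRF2 list was higher with DMF by a median log2 difference of 0.733 over 72 genes (0.762 within chip 1, 0.711 within chip 2; 0.646 in the 10 arrays). Of these genes 13 were called higher and 0 lower, 37 and 0 adjusted over the list alone, and 47 higher in the 10 arrays. The shift had an adjusted p of 4.62e-33, and 0.000191 with an estimated correlation. Gclc rose by 1.94 ± 0.20 (adjusted p = 0.00174) and Gclm by 2.02 ± 0.21 (adjusted p = 0.00171) among the 20 glutathione genes (median 0.741, 7 called, 11 adjusted over the list alone). Nqo1 rose by 1.5 ± 0.24 (adjusted p = 0.0303), Aldh3a1 by 1.85 and Entpd5 by 1.57 among the 20 quinone and aldehyde genes (median 0.823, 4 called, 13 adjusted over the list alone). Blvrb rose by 2.17 (9 heme and iron genes, median 0.757, 1 called, 5 adjusted over the list alone) and Srxn1 by 2.14 ± 0.18 (adjusted p = 0.000652; 8 thioredoxin genes, median 0.625, 1 called, 2 adjusted over the list alone). Txnrd1 differed by 2.25 ± 0.45 (adjusted p = 0.0912, with 1.68 and adjusted p = 0.000231 in the 10 arrays) and G6pdx by 0.12 ± 0.20 (adjusted p = 0.825). In the 10 arrays the mean log2 signal of G6pdx was 10.5 with DMSO and 10.85 with DMF. In the NADPH supply group (7 tested, median 0.701, 0 called by limma, 3 adjusted over the list alone) Pgd differed by 0.73 (adjusted p = 0.0674), and among 8 regulators (median 0.265, 0 called by limma, 2 adjusted over the list alone) Mafg by 0.82 (adjusted p = 0.103). Shifts had adjusted p-values of 6.47e-19 for glutathione (0.000515 with an estimated correlation), 1.55e-17 for quinones (0.000571), 7.79e-05 for heme and iron (0.0288) and 0.000223 for NADPH supply (0.0288). The thioredoxin call (adjusted p = 4.25e-05) ended at adjusted p = 0.0574 with an estimated correlation, and the regulators' call (adjusted p = 0.00691) at adjusted p = 0.0756 with an estimated correlation. These values were 0.0407 and 0.0541 in the 10 arrays, where the heme and iron call was lost at 0.0506. In the 10 arrays the thioredoxin median was 0.186. The bounds given for Gsta3 exceed its list's median under every compound, so none of these medians depends on its fitted value.

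**Figure D3:**
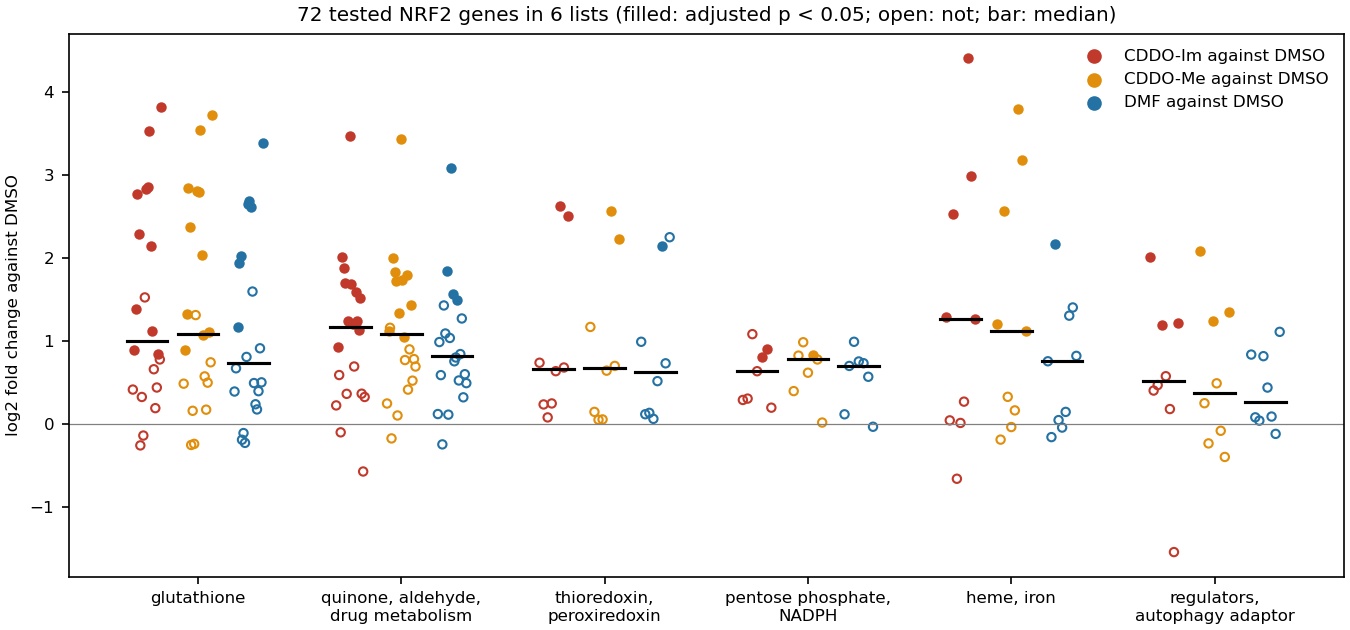
Log2 difference against DMSO of the 72 tested NRF2 pathway genes in 6 lists, one column of points per compound; filled points were called in limma and open points were not, and bars mark list medians. The joined medians were 0.825 for CDDO-Im, 0.863 for CDDO-Me and 0.733 for DMF, with 0 genes called lower.

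Trib3, a pseudokinase gene induced by ATF4, rose by 1.67 ± 0.19 with CDDO-Im, 1.73 ± 0.19 with CDDO-Me and 2.01 ± 0.19 with DMF (adjusted p = 0.00156, 0.00185 and 0.00125). Chac1, which degrades glutathione, rose by 1.17, 1.32 and 1.63 in that order, and the amino acid carrier subunit Slc3a2 by 2.40 with CDDO-Im (1.64 in the 10 arrays) and 2.22 with CDDO-Me. Of 22 ATF4 genes 3, 3 and 2 were called higher (7, 4 and 3 adjusted over the list alone), with medians of 0.301, 0.229 and 0.357. The adjusted p was 0.000223, 0.0017 and 1.06e-08, and every call was lost, with adjusted p = 0.19, 0.238 and 0.0574 with an estimated correlation. The CDDO-Im median was 0.171 in the 10 arrays. For DMF the value there was 0.0288, with a median of 0.413 and 8 members called (14 adjusted over the list alone). Of 19 heat shock genes limma called 0 for each compound (1, 1 and 0 adjusted over the list alone). These genes lay at -0.41 on DMSO replicate 1, with 7 under -1 and 1 over 1. Their medians were 0.237, 0.145 and 0.0885, with calls for CDDO-Im and CDDO-Me (adjusted p = 0.022 and 0.0123) that ended at adjusted p = 0.213 and 0.188 with an estimated correlation, and adjusted p = 0.101 for DMF. Bag3, the cochaperone with the smallest p there, differed by 0.64, 0.68 and 0.41 (adjusted p = 0.101, 0.124 and 0.658). Of 17 ER chaperone genes limma called 0, with 0, 0 and 2 adjusted over the list alone, medians of 0.147, 0.208 and 0.278 and adjusted p = 0.919, 0.102 and 0.00205. The DMF call ended at adjusted p = 0.344 with an estimated correlation, but in the 10 arrays it was kept at 0.0327, with a median of 0.207 and 5 members called (7 adjusted over the list alone). Sdf2l1 differed by -0.96 with CDDO-Im (adjusted p = 0.375; -0.12 and adjusted p = 0.523 in the 10 arrays) and Herpud1 by 0.52 with CDDO-Me and 0.77 with DMF (adjusted p = 0.373 and 0.15). Of 28 proteasome genes 0 were called, also adjusted over the list alone, with medians of 0.228, 0.121 and 0.0918 and adjusted p = 0.0174, 0.0124 and 0.071. Both calls ended, at adjusted p = 0.433 and 0.419 with an estimated correlation. These genes lay at -0.39 on DMSO replicate 1, and their medians in the 10 arrays were 0.0709, 0.0673 and 0.0235. Psmd11 differed by 0.56 with CDDO-Im and 0.66 with CDDO-Me (adjusted p = 0.333 and 0.366), and Psmc6 by 0.74 with DMF (adjusted p = 0.661).

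Cytokine and immediate early genes gave a few single calls. Il33, an epithelial alarmin, rose by 1.74 ± 0.30 and the chemokine gene Cxcl1 by 1.27 ± 0.23 with CDDO-Im (adjusted p = 0.0173 and 0.023). Egr1 rose by 2.19 ± 0.37 and the phosphatase gene Dusp1 by 1.86 ± 0.31 with CDDO-Im (adjusted p = 0.0148 and 0.0153), and Klf2 fell by 1.00 ± 0.17 with CDDO-Me (adjusted p = 0.0229). Fosl2 rose by 1.17 with CDDO-Im and 1.03 with CDDO-Me, though its probes differed in sign. Of 20 NF-kB targets 2 were called higher with CDDO-Im and 0 with the others, and adjusted over the list alone 2 were higher with CDDO-Im, 2 higher and 4 lower with CDDO-Me, and 1 higher with DMF. The medians were -0.0748, -0.249 and -0.0345 (adjusted p = 0.909, 0.103 and 0.977), and for CDDO-Im the median and the test were negative while the mean was 0.131, and for DMF the mean (0.0651) and the test were positive. With 10 arrays the CDDO-Me list was called (-0.174, adjusted p = 0.0353) but not with an estimated correlation (0.157). Tnfaip2 differed by -0.65 with CDDO-Me and Il33 by 1.52 with DMF (adjusted p = 0.161 and 0.106). Of 19 immediate early genes 3 were called higher with CDDO-Im, 1 higher and 1 lower with CDDO-Me and 1 higher with DMF (4 higher, 3 higher and 1 lower, and 4 higher adjusted over the list alone). Their medians were 0.335, 0.216 and 0.327 (adjusted p = 0.0191, 0.261 and 0.00194), with both calls lost at adjusted p = 0.186 and 0.0769 with an estimated correlation. Over the 10 arrays the medians were 0.177, 0.0846 and 0.141. Of 17 interferon genes limma called 0 (0 adjusted over the list alone), with medians of 0.0421, 0.021 and 0.0389 and adjusted p = 0.939, 0.799 and 0.91. For CDDO-Me and DMF the mean and the test were negative (means -0.0193 and -0.0318). The medians in the 10 arrays were -0.0594, -0.0793 and -0.0889. Oasl1 differed by 0.50, -0.53 and 0.70 (adjusted p = 0.332, 0.456 and 0.336). Of 14 STAT3 pathway genes Socs3, a feedback inhibitor of cytokine signalling, rose by 0.96 ± 0.14 with CDDO-Im (adjusted p = 0.00617) and differed by 0.62 and 0.52 with the others (adjusted p = 0.0895 and 0.303). That list had 1, 0 and 0 calls (1, 1 and 0 adjusted over the list alone), medians of 0.0443, 0.0289 and 0.145 and adjusted p = 0.939, 0.91 and 0.734, with means of -0.0157 for CDDO-Im and -0.112 for CDDO-Me and a negative test for CDDO-Me; in the 10 arrays the medians were 0.00978, 0.0184 and 0.0271.

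Vegfa, the vascular growth factor, rose by 1.26 ± 0.19 with CDDO-Im, 1.01 ± 0.20 with CDDO-Me and 1.35 ± 0.20 with DMF (adjusted p = 0.00863, 0.0398 and 0.0195), and the glucose carrier Slc2a1 by 0.78 with CDDO-Im. Ccn2, a matricellular growth factor gene, fell by 0.95 ± 0.15 with CDDO-Im and by 1.55 ± 0.15 with CDDO-Me (adjusted p = 0.0103 and 0.000777). Mmp13 rose by 1.76 and 1.68, though its probes differed in sign for CDDO-Me, and Id2 fell by 0.86 with CDDO-Me. Acss2, an acetyl-CoA synthetase gene, rose by 2.45 ± 0.50 with CDDO-Im (adjusted p = 0.0405; 1.86 in the 10 arrays) and differed by 2.42 and 2.04 with the others (adjusted p = 0.0645 and 0.248). Of 22 hypoxia and glycolysis genes 2, 1 and 1 were called higher (3 higher, 4 higher and 1 lower, and 5 higher adjusted over the list alone). Their medians were 0.111, 0.16 and 0.191 (adjusted p = 0.101, 0.0479 and 0.000219), and both calls were lost at adjusted p = 0.331 and 0.103 with an estimated correlation. That value in the 10 arrays was 0.0407 for CDDO-Im, 0.0886 for CDDO-Me and 0.0247 for DMF, with medians of 0.128, 0.0731 and 0.234. Of 20 TGF-beta and matrix genes 1 was called higher and 2 lower with CDDO-Im and with CDDO-Me, and 0 with DMF (2 and 3, 1 and 2, and 1 and 1 adjusted over the list alone). Their medians were -0.17, -0.246 and -0.313 (adjusted p = 0.0378, 0.0429 and 0.0428), and all 3 calls were lost at adjusted p = 0.204, 0.209 and 0.209 with an estimated correlation; under median scaling the CDDO-Me median was 0.0362, against 0.219 for all genes, and in the 10 arrays it was -0.136 with adjusted p = 0.125. Mmp13 differed by 1.27 with DMF (adjusted p = 0.118). Of 11 fatty acid genes 1, 0 and 0 were called (1, 1 and 1 adjusted over the list alone), with medians of 0.0327, 0.179 and 0.375 and adjusted p = 0.828, 0.287 and 0.00664, the last lost at adjusted p = 0.413 with an estimated correlation. Fatty acid genes lay low on DMSO replicate 1, and the DMF median was 0.168 in the 10 arrays. Of 22 cholesterol genes limma called 0 (0 adjusted over the list alone), with medians of 0.121, -0.121 and 0.196 and adjusted p = 0.909, 0.679 and 0.00565. The DMF call ended at adjusted p = 0.0574 with an estimated correlation, with 0.0288 in the 10 arrays. The triterpenoid medians in the 10 arrays were 0.0497 and -0.0437. Mvk differed by 0.79 with CDDO-Im, Fdps by -0.25 with CDDO-Me and Msmo1 by 1.34 with DMF (adjusted p = 0.257, 0.706 and 0.413).

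Growth and cell type genes gave a few single calls. Aqp5, a water channel of alveolar epithelium, fell by 0.78 ± 0.15 with CDDO-Im and by 1.25 ± 0.16 with CDDO-Me (adjusted p = 0.0319 and 0.00421), and Cd14, a receptor for bacterial lipid, fell by 1.43 ± 0.26 with CDDO-Me (adjusted p = 0.0257). Esam, an adhesion molecule gene, rose by 2.75, 2.11 and 1.61 with CDDO-Im, CDDO-Me and DMF, or at least 5.18-fold, 3.29-fold and 2.32-fold. Pdgfra rose by 1.80 with CDDO-Im and 1.30 with CDDO-Me, at least 2.32-fold and 1.54-fold, and was not called with DMF (adjusted p = 0.432). Of 32 S and G2/M genes limma called 0 (0 adjusted over the list alone), with medians of -0.151, -0.00688 and -0.0657 and adjusted p = 0.0203, 0.455 and 0.422. The CDDO-Im call ended at adjusted p = 0.308 with an estimated correlation (0.0407 in the 10 arrays), and the means for CDDO-Me (0.000965) and DMF (0.0204) were positive; in the 10 arrays both medians were lower (-0.131 and -0.114) and called (adjusted p = 0.00366 and 0.0065), though not with an estimated correlation (0.0607 and 0.0685). Tk1 differed by -0.51, -0.45 and -0.39 (adjusted p = 0.138, 0.312 and 0.583). Of 19 p53 targets limma called 0 (1, 1 and 0 adjusted over the list alone), with medians of 0.218, 0.0761 and 0.116 and adjusted p = 0.121, 0.416 and 0.056. These genes lay at -0.40 on DMSO replicate 1, and in the 10 arrays their medians were 0.114, 0.0524 and 0.214, the last called (adjusted p = 0.0173) but not with an estimated correlation (0.096). Plk2 differed by 1.13 and 1.18 with the triterpenoids and Gadd45a by 0.87 with DMF (adjusted p = 0.056, 0.0657 and 0.523). Of 16 apoptosis regulators 0 were called (0 adjusted over the list alone), with medians of -0.194, -0.183 and 0.0245, the last against a mean of -0.0716, and adjusted p = 0.138, 0.138 and 0.658. With 10 arrays they were -0.122, -0.126 and 0.0156, called for CDDO-Me (adjusted p = 0.0448, 0.139 with an estimated correlation). Bcl2l11 differed by -0.43 with CDDO-Me (adjusted p = 0.339). Limma called 0 of 5 histone genes, 0 of 4 metallothionein and zinc genes and 0 of 2 aryl hydrocarbon receptor targets, the counts adjusted over the list alone included. Their medians were -0.114, -0.106 and -0.00886 for histones (adjusted p = 0.101, 0.124 and 0.594), 0.399, 0.196 and 0.158 for metallothioneins (adjusted p = 0.21, 0.396 and 0.847), and 0.167, 0.0785 and -0.0191 for receptor targets (adjusted p = 0.83, 0.909 and 0.972). In the 10 arrays they were -0.321, -0.372 and -0.122 for histones, called for CDDO-Im and CDDO-Me but not with an estimated correlation (0.0926 and 0.0886), -0.0502, 0.0617 and -0.0973 for metallothioneins, and -0.244, -0.152 and -0.25 for receptor targets.

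H2az1 differed by -0.54 with CDDO-Im and -0.34 with DMF and H2ax by -0.58 with CDDO-Me (adjusted p = 0.304, 0.661 and 0.484). Slc30a1, a zinc exporter, differed by 0.98 and 0.95 with the triterpenoids and Mt2 by 0.43 with DMF (adjusted p = 0.334, 0.54 and 0.661). Ahrr differed by 0.35 and 0.16 and Cyp1b1 by -0.03 in the same order (adjusted p = 0.571, 0.848 and 0.983). Of 12 lung epithelium markers 1, 1 and 0 were called lower (2, 2 and 0 adjusted over the list alone), with medians of -0.0177, -0.089 and -0.312 and adjusted p = 0.102, 0.0174 and 0.267. The CDDO-Me call ended at adjusted p = 0.136 with an estimated correlation, and its median was 0.179 under median scaling (0.219 for all genes there), 0.00234 without a filter on dim probes and -0.294 in the 10 arrays. These markers lay at 0.40 on DMSO replicate 1 and 0.34 on CDDO-Im replicate 2. The CDDO-Im median in the 10 arrays was -0.252 and called (adjusted p = 0.00396, 0.139 with an estimated correlation), and that of DMF was -0.12. Krt7 differed by -0.52 with DMF (adjusted p = 0.661). Of 11 fibroblast markers 1, 1 and 0 were called higher (1 higher and 1 lower, 1 higher, and 0 adjusted over the list alone), with medians of 0.00015, -0.0498 and -0.0186 and adjusted p = 0.763, 0.739 and 0.978, and with positive means for CDDO-Me (0.0919) and DMF (0.00868). Of 5 leukocyte markers 0, 1 and 0 were called, lower (1 higher and 2 lower, 1 and 1, and 0 adjusted over the list alone), with medians of 0.289, -0.0238 and 0.0302 and adjusted p = 0.801, 0.709 and 0.909, and with a negative test beside positive medians for CDDO-Im and DMF. They lay at 0.66 on CDDO-Im replicate 2, and the CDDO-Im median was -0.169 in the 10 arrays. Cd14 differed by -1.04 with CDDO-Im and -0.71 with DMF (adjusted p = 0.0819 and 0.573). Of 6 endothelial markers 1 was called higher for each compound (1 adjusted over the list alone), with medians of 0.0521, -0.106 and -0.0404 and adjusted p = 0.417, 0.662 and 0.909, and with positive means for CDDO-Me (0.231) and DMF (0.0681). They lay at 0.96 on CDDO-Im replicate 2, and the CDDO-Im median was -0.179 in the 10 arrays.

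Hmox1, Slc7a11, Cbr3 and Gsta3 stood among genes that several compounds changed in the same direction. CDDO-Im and CDDO-Me shared 129 genes called higher and 34 called lower, 163 in all, where independent calls would share 1.93 and 0.208. CDDO-Im and DMF shared 43 higher and 3 lower (0.609 and 0.0117 by chance), and CDDO-Me and DMF 42 higher and 3 lower (0.44 and 0.012 by chance). No gene was called in opposite directions with 12 arrays, and 2, 0 and 8 were with 10. The compounds share their 3 DMSO arrays, which alone ties the comparisons, so unchanged groups sharing controls were simulated 50 times. They shared 0 called genes on average, but unchanged groups have hardly any calls to share, so that 0 is no measure for the shared counts. The covariance of log2 differences was 0.162 against a simulated 0.135 for CDDO-Im and CDDO-Me, 0.149 against 0.135 for CDDO-Im and DMF, and 0.152 against 0.109 for CDDO-Me and DMF. The correlation, in contrast, lay below the simulated one in each pair (0.8 against 0.805, 0.768 against 0.802 and 0.885 against 0.943), as did the share of genes with the same sign (76.9% against 79.7%, 76.1% against 79.6% and 86% against 89.3%). The covariance in the 10 arrays was 0.0904 against 0.0188, 0.0701 against 0.0188 and 0.0639 against 0.0175. The correlation there was 0.895 against 0.718, 0.812 against 0.704 and 0.772 against 0.727, and the share 80.7% against 75.5%, 78.5% against 74.7% and 77.6% against 75.9%. Because 3 DMSO arrays cannot be divided so that each side keeps at least 2, part of the shared calls may come from the shared controls. Leaving out 1 array moved the shared counts from 41 (without CDDO-Me replicate 1) to 246 (without DMSO replicate 1) for CDDO-Im and CDDO-Me, and from 23 (without DMF replicate 1) to 109 and 103 (without CDDO-Im replicate 2) for DMF with CDDO-Im and with CDDO-Me. The 10 arrays shared 588 higher and 457 lower genes between CDDO-Im and CDDO-Me, 428 and 347 between CDDO-Im and DMF, and 398 and 314 between CDDO-Me and DMF.

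**Figure D4:**
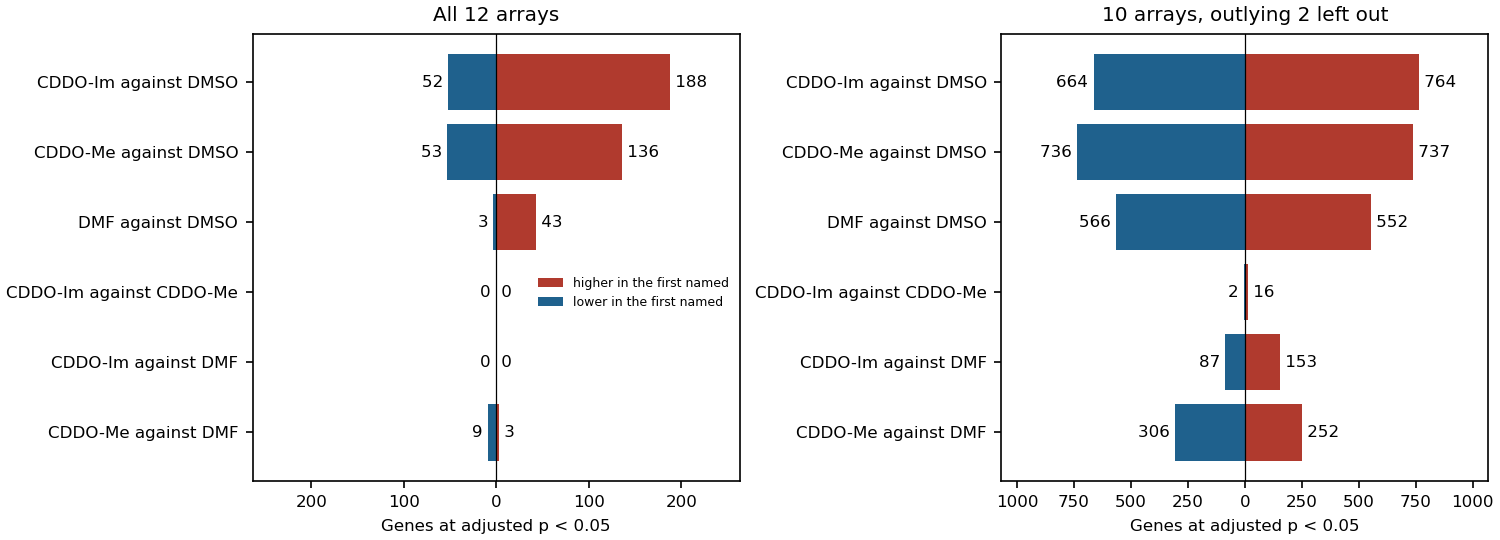
Number of genes called higher (right, red) and lower (left, blue) in limma for each of the 6 comparisons, with 12 arrays in the left panel and with DMSO replicate 1 and CDDO-Im replicate 2 left out in the right panel. CDDO-Im against DMSO had 188 higher and 52 lower in the first and 764 and 664 in the second.

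Synpo, Rasl11b and Oasl1 were among the 5 genes with the smallest p between the triterpenoids, at 0.05 µM CDDO-Im and 0.1 µM CDDO-Me, though none passed the threshold. Synpo, an actin-binding protein gene, was 1.56 higher with CDDO-Im (95% interval 0.99 to 2.13, adjusted p = 0.765), Rasl11b, a small GTPase gene, 1.03 (0.65 to 1.42, adjusted p = 0.765) and Oasl1, an antiviral gene, 1.03 (0.59 to 1.46, adjusted p = 1). Pfkfb4 was 0.68 higher (0.39 to 0.97, adjusted p = 1) and the unnamed locus LOC240672 0.81 (0.50 to 1.12, adjusted p = 0.765). Hmox1 differed by 0.61 (-0.28 to 1.49), Slc7a11 by 0.10 (-0.29 to 0.49), Nqo1 by -0.21 (-0.74 to 0.32), Gclc by -0.08 (-0.53 to 0.36), Gclm by -0.08 (-0.54 to 0.38), Txnrd1 by 0.27 (-0.73 to 1.27), Srxn1 by 0.05 (-0.36 to 0.46) and G6pdx by -0.11 (-0.56 to 0.35). Of 13280 genes limma called 0, with 206 at an unadjusted p under 0.05, and in the 10 arrays 16 were higher and 2 lower with CDDO-Im. Within each chip, where 1 of these groups had 1 array, limma called 0, with 3 genes at an unadjusted p under 0.05 in chip 1 and 1018 in chip 2. The joined NRF2 list had 0 calls (0 adjusted over the list alone) and a median of 0.027 against a mean of -0.0163 and a negative test (adjusted p = 0.734). The NF-kB list was 0.215 higher with CDDO-Im (adjusted p = 0.0101, lost at adjusted p = 0.0756 with an estimated correlation) and -0.0971 under median scaling, and the immediate early list 0.212 higher (adjusted p = 0.00812, lost at adjusted p = 0.131 with an estimated correlation and kept at 0.0288 in the 10 arrays) and -0.0638 under median scaling. That scaling put the median of all genes at -0.203, and both lists were still called under it (adjusted p = 0.00178 for each). ER chaperones (-0.117, adjusted p = 0.017) and S and G2/M genes (-0.132, adjusted p = 0.0101) were lower with CDDO-Im and lost their calls at adjusted p = 0.433 and 0.261 with an estimated correlation; without CDDO-Im replicate 2 the ER chaperone median was 0.0258. Cholesterol synthesis genes, at 0.104 (adjusted p = 0.287), reached 0.183 in the 10 arrays with adjusted p = 0.0288 with an estimated correlation.

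Hmox1 was 3.10 ± 0.40 higher with 0.05 µM CDDO-Im than with 15 µM DMF (95% interval 2.22 to 3.99, adjusted p = 0.0571), just outside the threshold. Fgfbp1, a carrier of fibroblast growth factors, was 1.07 ± 0.13 higher (0.77 to 1.37) and Dppa5a 1.09 ± 0.14 (0.78 to 1.41), each with adjusted p = 0.0571. Edn2, an endothelin gene, was 1.63 ± 0.22 higher (1.13 to 2.12, adjusted p = 0.0693). Gclc differed by 0.83 (0.39 to 1.28), Slc7a11 by 0.43 (0.04 to 0.82), Srxn1 by 0.48 (0.07 to 0.89), Gclm by 0.27 (-0.19 to 0.73), Nqo1 by 0.09 (-0.43 to 0.62), Txnrd1 by 0.25 (-0.74 to 1.25) and G6pdx by 0.17 (-0.28 to 0.63). Limma called 0 genes, with 441 at an unadjusted p under 0.05, while in the 10 arrays 153 were higher and 87 lower. The count was 36 without DMSO replicate 1, 2 without CDDO-Im replicate 2 and 1 without DMSO replicate 2. Within each chip, where 1 of these groups had 1 array, limma called 0, with 5 genes at an unadjusted p under 0.05 in chip 1 and 1584 in chip 2.

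The joined NRF2 list was higher with CDDO-Im than with DMF by a median of 0.187, with 0 calls (4 adjusted over the list alone) and an adjusted p of 3.94e-06, and 0.0109 with an estimated correlation. Its glutathione (0.242, adjusted p = 6.13e-05) and heme and iron groups (0.373, adjusted p = 7.19e-05) had calls kept at 0.0186 and 0.0288 with an estimated correlation, which were 0.0407 and, lost, 0.0607 in the 10 arrays. Cholesterol synthesis genes were lower with CDDO-Im by a median of -0.202 (22 tested, 0 called by limma, 0 adjusted over the list alone, adjusted p = 0.000559), and 0.0288 with an estimated correlation. Insig1, a regulator of sterol synthesis, differed by -1.19 and had the smallest p of that list (adjusted p = 0.973). ER chaperones (-0.375, adjusted p = 1.73e-05), fatty acid synthesis (-0.187, adjusted p = 0.00473), S and G2/M genes (-0.069, adjusted p = 0.0191) and hypoxia targets (-0.0881, adjusted p = 0.0296) were lower with CDDO-Im and lost their calls at adjusted p = 0.213, 0.387, 0.303 and 0.3 with an estimated correlation. ER chaperone and fatty acid genes lay low on CDDO-Im replicate 2 (-0.57 and -0.67), and in the 10 arrays their medians were -0.116 and -0.0908, the former kept at 0.0407 with an estimated correlation.

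Edn1, Edn2 and Fgfbp1 were higher, and Ivl, Sox9 and 7 other genes lower, with 0.1 µM CDDO-Me than with 15 µM DMF. Edn1, the precursor gene of endothelin-1, was 1.49 ± 0.18 higher with CDDO-Me (adjusted p = 0.0318), Edn2 1.53 ± 0.21 (adjusted p = 0.0435) and Fgfbp1 0.95 ± 0.13 (adjusted p = 0.0435). Ivl, involucrin of the cornified envelope, was -2.48 ± 0.30 different (adjusted p = 0.0318), at least 4.37-fold lower with CDDO-Me, whose 3 arrays did not detect it. Mgat3, a glycosyltransferase gene, fell by 1.98 ± 0.28 relative to DMF (adjusted p = 0.0435), Sox9 by 1.54 ± 0.18, Rasl11b by 1.48 ± 0.17 and Gp49a by 1.85 ± 0.23 (each adjusted p = 0.0318), and Synpo by 1.74 ± 0.25 (adjusted p = 0.0435). Pfkfb4 (-0.99, adjusted p = 0.0318) was lower too, as were Fcgr3 (-1.24) and Cldn2 (-1.04), named after their values were seen. Hmox1 was 2.49 higher with CDDO-Me (1.64 to 3.35) and missed the threshold (adjusted p = 0.061), as did Oasl1 at -1.23 (adjusted p = 0.061) and Csf2, which no CDDO-Me array detected and which was at least 2.47-fold lower (adjusted p = 0.093). Gclc differed by 0.91 (0.48 to 1.35), Srxn1 by 0.43 (0.03 to 0.82), Slc7a11 by 0.33 (-0.05 to 0.71), Gclm by 0.35 (-0.10 to 0.80), Nqo1 by 0.30 (-0.21 to 0.82), Txnrd1 by -0.02 (-0.98 to 0.95) and G6pdx by 0.28 (-0.16 to 0.72). Limma called 3 genes higher and 9 lower of 13280, 12 in all and each with the same sign within both chips, and the 10 arrays gave 252 and 306. Within chip 2, with 2 arrays of each, the count was 62, and within chip 1, with 1 array of each, limma called 0, with 7 at an unadjusted p under 0.05. With the replicate number as a block 1 of the 12 was still called, with or without the chip term. The count was 79 without DMSO replicate 1 and 51 without CDDO-Im replicate 2, but 0 in limma without DMSO replicate 3, CDDO-Im replicate 1 or 3, any CDDO-Me replicate or any DMF replicate, with 205 to 321 genes at an unadjusted p under 0.05. Neither CDDO-Me nor DMF holds an outlying array, and fitted with only these 2 groups limma called 450 genes. The median standard error of this difference was 0.242 with 12 arrays and 0.0855 with 10.

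**Figure D5:**
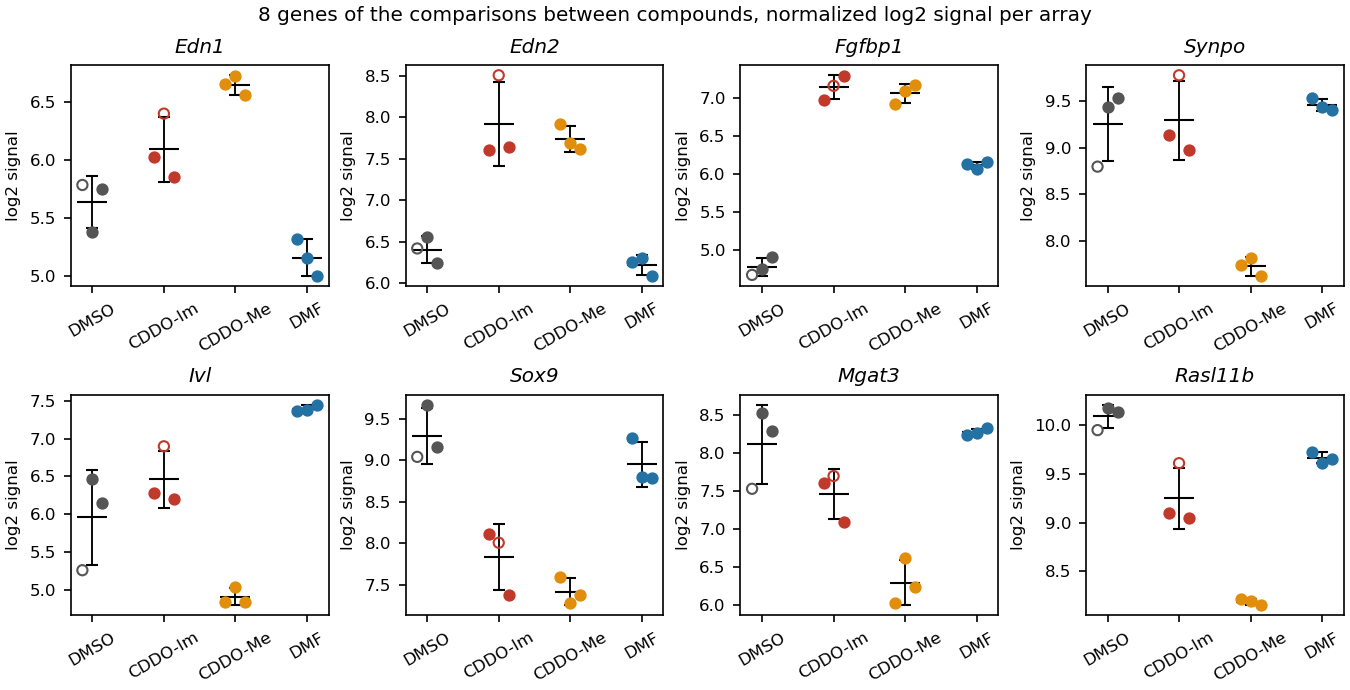
Log2 signal of Edn1, Edn2, Fgfbp1, Synpo, Ivl, Sox9, Mgat3 and Rasl11b on each array (circles; open for DMSO replicate 1 and CDDO-Im replicate 2), with the group mean and its SD (bars, 3 arrays per group). Mean Ivl was 4.91 with CDDO-Me and 7.40 with DMF, and mean Edn1 6.65 and 5.16.

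NRF2 targets and cholesterol genes also differed as lists between CDDO-Me and DMF. The joined NRF2 list was higher with CDDO-Me by a median of 0.166, with 0 calls in limma (4 adjusted over the list alone), an adjusted p of 1.48e-12 and 0.00154 with an estimated correlation. The glutathione (0.231, adjusted p = 1.7e-09), quinone (0.172, adjusted p = 9.18e-05) and heme and iron groups (0.302, adjusted p = 1.47e-07) kept their calls at 0.00298, 0.0192 and 0.0104 with an estimated correlation; in the 10 arrays these were 0.0407, 0.0551 and 0.0637, so that the last pair was lost. Cholesterol synthesis genes were lower with CDDO-Me by a median of -0.334 over 22 genes, with 0 called by limma (0 adjusted over the list alone, 15 in the 10 arrays), an adjusted p of 4.7e-10 and 0.00254 with an estimated correlation. Fdps, a prenyl diphosphate synthase gene, differed by -0.46 (adjusted p = 0.573). ATF4 targets (-0.13, adjusted p = 3.02e-05), immediate early genes (-0.152, adjusted p = 0.000977), lung epithelium markers (-0.137, adjusted p = 0.00444) and fatty acid synthesis (-0.131, adjusted p = 0.0205) were lower with CDDO-Me and lost their calls at adjusted p = 0.136, 0.0689, 0.0769 and 0.461 with an estimated correlation. The same was seen for NF-kB targets (-0.0394, adjusted p = 0.0029), hypoxia targets (-0.0812, adjusted p = 0.00639) and ER chaperones (-0.074, adjusted p = 0.00924), lost at adjusted p = 0.0529, 0.213 and 0.42 with an estimated correlation (0.106, 0.0407 and 0.0568 in the 10 arrays). Under median scaling those medians were 0.0608, 0.0389 and 0.03, below the 0.108 of all genes, with adjusted p = 0.00013, 0.103 and 0.0425, and the NF-kB median was 0.0246 without a filter on dim probes. Of 174 list tests 64 were called and 24 kept their call with an estimated correlation, 22 of them in NRF2 lists and 2 in the cholesterol list. In the 10 arrays 52 tests of the 22 other lists were called and 12 kept their call, in the cholesterol, hypoxia, ER chaperone, ATF4, immediate early and S and G2/M lists. With 12 arrays the median, the mean and the test differed in sign in 30, of which 0 were called.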

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

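Counts of called genes depended on the settings far more than directions did. All 136 called values among 296 named gene values kept their sign under the 19 planned settings that give gene values, 12 that left out an array and 2 added ones. They were picked as called in the same arrays, and each called gene had the same sign within both chips. Kept signs are therefore no separate test of direction. With only the 2 groups compared, 106 of the 136 lost their call. Of the 136, 74 were called whichever array was left out and 68 under each of the 16 planned settings that fit all 12 arrays. Within chip 1, which holds 6 arrays, limma called 0 of them. That chip held both DMSO replicate 1 and CDDO-Im replicate 2, the arrays that stood apart. The NRF2 shifts were called in 96 of 96 values, with medians of 0.682 to 0.944 for CDDO-Im, 0.744 to 1.14 for CDDO-Me and 0.506 to 0.92 for DMF. The 2 settings of 10 arrays were added after results were seen. Limits lie in 3 arrays per group, in 2 arrays that enlarge the spread, in controls shared by the compounds and in labels that do not say where replicates came from. The counts below are of called genes, against 240, 189 and 46 for CDDO-Im, CDDO-Me and DMF against DMSO, 0, 0 and 12 for CDDO-Im against CDDO-Me, CDDO-Im against DMF and CDDO-Me against DMF, and overlaps of 163, 46 and 45; the causes of the movements were not tested unless said.

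Under no background correction the counts were 4 for CDDO-Im against DMF and 7 for CDDO-Me against DMF, and with a background offset of 50 the former was 3. Cyclic loess gave 87 for DMF against DMSO and 19 for CDDO-Me against DMF, with overlaps of 82 (CDDO-Im and DMF) and 74 (CDDO-Me and DMF). With no filter on dim probes CDDO-Im against DMF gave 6, and the medians of lung epithelium markers for CDDO-Me against DMSO and of NF-kB targets for CDDO-Me against DMF turned to 0.00234 and 0.0246. The series matrix values gave 86 for DMF against DMSO, 12 for CDDO-Im against DMF and 22 for CDDO-Me against DMF, with overlaps of 81 and 77 for DMF with CDDO-Im and with CDDO-Me.

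Median scaling gave 105 for CDDO-Im against DMSO, 121 for CDDO-Me against DMSO, 4 for CDDO-Me against DMF and an overlap of CDDO-Im and CDDO-Me of 87. It left medians over all genes of 0.219 for CDDO-Me against DMSO and -0.203 for CDDO-Im against CDDO-Me, so by construction small list shifts turned with it. For CDDO-Me against DMSO the TGF-beta and matrix median became 0.0362 and that of lung epithelium markers 0.179. For CDDO-Im against CDDO-Me that of NF-kB targets became -0.0971 and that of immediate early genes -0.0638. For CDDO-Me against DMF those of ER chaperones, NF-kB targets and hypoxia targets became 0.03, 0.0608 and 0.0389. The share called higher was 82.6% for CDDO-Me against DMSO, against 72%, and 50% for CDDO-Me against DMF, against 25%.

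No chip term gave 80 for DMF against DMSO, 5 for CDDO-Im against DMF and 29 for CDDO-Me against DMF, with overlaps of 78 and 72 for DMF with CDDO-Im and with CDDO-Me. The chip as random block gave 83 for DMF against DMSO, 2 for CDDO-Im against DMF and overlaps of 78 and 74, with a consensus correlation of -0.0824 and no list tests. Single chips hold 1 array of some groups, whose spread there is that of other groups. Chip 1 also holds both outlying arrays. Within chip 1 limma called 0 genes in every comparison, with overlaps of 0, 0 and 0 and with 212, 87 and 43 genes at an unadjusted p under 0.05 for the compounds against DMSO and 3, 5 and 7 between compounds. Within chip 2 the counts were 403 for CDDO-Me against DMSO, 147 for DMF against DMSO and 62 for CDDO-Me against DMF, with overlaps of 248, 121 and 120.

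A replicate block with chip term gave 109 for CDDO-Me against DMSO, 1 for CDDO-Me against DMF and an overlap of CDDO-Im and CDDO-Me of 102. The replicate block without chip term gave 1 for CDDO-Me against DMF. Deviations of same-numbered arrays correlated at -0.296 to 0.363 over 18 pairs (median 0.134), 10 of them over 0.1, and 7 of 12 arrays correlated best with one of their own number. The numbers were not taken as pairs, because not every pair was over 0.1 and the labels give the numbers no meaning. All 3 pairs of CDDO-Me and DMF were over 0.1 (0.345, 0.141 and 0.172), so paired samples stay open there, and number and chip run together, as arrays numbered 1 lie on chip 1 and those numbered 3 on chip 2. With the block the list calls of CDDO-Me against DMF were unchanged.

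Array quality weights gave 3633, 3124 and 3011 for CDDO-Im, CDDO-Me and DMF against DMSO, 236 for CDDO-Im against CDDO-Me, 816 for CDDO-Im against DMF and 970 for CDDO-Me against DMF, with overlaps of 2341, 2109 and 1874. The weights were estimated gene by gene, because the REML estimate did not converge to usable ones, so these counts rest on that method. Those of DMSO replicate 1 and CDDO-Im replicate 2 were 0.0322 and 0.0419, others 0.549 to 4.2. With only the 2 groups compared the counts were 3, 27 and 1 against DMSO and 450 for CDDO-Me against DMF, with overlaps of 3, 1 and 1. Overlaps at an adjusted p under 0.01 were 70, 27 and 27. With an estimated correlation 40 of 61 called list shifts besides the 3 lead ones were lost.

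Without DMSO replicate 1 the counts were 383, 301 and 108 against DMSO, 36 for CDDO-Im against DMF and 79 for CDDO-Me against DMF, with overlaps of 246, 102 and 94. Without DMSO replicate 2 CDDO-Im against DMF gave 1. Without DMSO replicate 3 they were 121, 64 and 24 against DMSO, 0 for CDDO-Me against DMF in limma (284 at an unadjusted p under 0.05) and overlaps of 58, 24 and 24. Without CDDO-Im replicate 2 they were 327 for CDDO-Me against DMSO, 121 for DMF against DMSO, 2 for CDDO-Im against DMF and 51 for CDDO-Me against DMF, with overlaps of 109 and 103 for DMF with CDDO-Im and with CDDO-Me, and the ER chaperone median for CDDO-Im against CDDO-Me was 0.0258, against -0.215 without CDDO-Im replicate 1.

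For CDDO-Me against DMF limma called 0 without CDDO-Im replicate 1 (321 at an unadjusted p under 0.05) or 3 (278). Without CDDO-Im replicate 3 CDDO-Im against DMSO gave 101, CDDO-Me against DMSO 127 and the overlaps were 83, 32 and 33. Without CDDO-Me replicate 1 the count was 42 for CDDO-Me against DMSO, 28 for DMF against DMSO and 0 for CDDO-Me against DMF, with overlaps of 41, 28 and 26. Without CDDO-Me replicate 2 they were 86, 33 and 0, with overlaps of 77, 33 and 30, and without CDDO-Me replicate 3 82, 32 and 0, with overlaps of 78, 32 and 30.

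Without DMF replicate 1 CDDO-Me against DMSO gave 114, DMF against DMSO 23 and CDDO-Me against DMF 0, with overlaps of 103, 23 and 23. Without DMF replicate 2 they were 112, 24 and 0, with overlaps of 102, 24 and 24, and without DMF replicate 3 115, 29 and 0, with overlaps of 103, 29 and 29.

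The 10 arrays, both outlying arrays left out, gave 1428, 1473 and 1118 against DMSO, 18 for CDDO-Im against CDDO-Me, 240 for CDDO-Im against DMF and 558 for CDDO-Me against DMF, with overlaps of 1045, 775 and 712. The 10 arrays, normalized again, gave 1394, 1455, 1071, 19, 236 and 547 in that order, with overlaps of 1030, 746 and 689.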

Other observations

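The wrong-label test and the fits of 10 arrays in this part were chosen after results were seen, and so were the genes of its first paragraphs that the naming rule did not reach. No list of these genes was tested. Slc1a4, a carrier of alanine and serine, rose by 2.76 ± 0.17 with CDDO-Im, 2.91 with CDDO-Me and 2.08 with DMF (limma adjusted p = 2.82e-05, 3.1e-05 and 0.000613), and Slc6a9, the glycine carrier, by 2.16, 2.04 and 1.72 (adjusted p = 0.000127, 0.000281 and 0.00171). Glutathione is made of glutamate, cysteine and glycine, and Slc7a11 brings in cystine. Gss, which joins glycine to the other parts, differed by 1.53, 1.31 and 0.81 and missed the threshold (adjusted p = 0.0771, 0.226 and 0.661), though in the 10 arrays it was 1.84, 1.74 and 1.24 higher.

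Krt5, a keratin gene of basal epithelium, rose by 1.49 ± 0.16 with CDDO-Im, 1.09 with CDDO-Me and 1.17 with DMF (limma adjusted p = 0.00123, 0.0106 and 0.0165), at least 1.91-fold, 1.41-fold and 1.49-fold as no DMSO array detected it, and Krt6b by 1.35, 0.95 and 1.19 (adjusted p = 0.00247, 0.0229 and 0.0164). Krt16 rose by 2.89 and 2.64 with the triterpenoids (adjusted p = 0.0116 and 0.0265) and differed by 1.70 with DMF (adjusted p = 0.357). Eomes, a T-box transcription factor gene, rose by 3.00, 2.72 and 1.53 (adjusted p = 8.26e-05, 0.000272 and 0.0201). Has2, which makes hyaluronan, fell by 1.26 with CDDO-Me (adjusted p = 0.00716) and differed by -0.31 with DMF (adjusted p = 0.661). Its mean log2 signal in the 10 arrays was 6.574 with DMSO, 5.131 with CDDO-Im, 5.225 with CDDO-Me and 6.177 with DMF. Hs3st1, a heparan sulfate sulfotransferase gene, fell by 1.23 with CDDO-Im and 1.20 with CDDO-Me (adjusted p = 0.00522 and 0.00786) and differed by -0.24 with DMF (adjusted p = 0.661).

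The called counts were set against every way of splitting the 6 arrays of a comparison, of which there are 10, too few for a share under 0.05. The real grouping gave 240, 189 and 46 genes for CDDO-Im, CDDO-Me and DMF against DMSO and 12 for CDDO-Me against DMF, and the highest of the other splits gave 0 in each, so that 1 split of 10 was as large. For CDDO-Im against CDDO-Me and CDDO-Im against DMF the real and the highest other count were both 0, so that 10 of 10 were as large. In the 10 arrays CDDO-Me against DMF gave 558 against at most 1, again 1 split. A chance assignment of arrays to groups can therefore be neither excluded nor shown by these counts.

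DMSO replicate 1 and CDDO-Im replicate 2 stood apart from the other 10 arrays, with deviations over 1 log2 unit in 26% and 20.2% of genes against at most 0.286% elsewhere. An exchange of labels between these 2 arrays was excluded by their place on the axis of the 72 NRF2 genes from DMSO (0) to CDDO-Im (1). DMSO replicate 1 lay at -0.0905 (-0.269 to 0.0571) and CDDO-Im replicate 2 at 0.908 (0.821 to 0.998). An exchange of CDDO-Im replicate 2 with a CDDO-Me or DMF array was not tested, as those compounds also raised these genes. Noise independent between single probes would not make paired probes of a gene deviate alike. The deviations of paired probes of 4059 genes correlated at 0.274 (0.241 to 0.308) and 0.349 (0.315 to 0.384), above the 0.0465 to 0.183 of other arrays. These values argue against such noise as the only source. They lay below the 0.669 to 0.799 of treatment effects and below the level set beforehand for excluding it, so such noise as a part of the deviations stayed open. Admixed RNA from other cells, in amounts no larger than the cells' own, lowers a gene by at most 1 log2 unit. Against at most 1 on other arrays, 125 and 47 of the 1000 brightest genes lay lower than that. These counts argue against admixture alone in such amounts. They cannot exclude it, because the bound holds for RNA amounts and the values were background corrected and quantile normalized. Larger amounts were not tested. Endothelial and leukocyte markers lay at 0.96 and 0.66 on CDDO-Im replicate 2, and at 0.12 and 0.395 on DMSO replicate 1. Admixture together with noise also stayed open, as noise carries genes past that bound too. Degraded RNA was not tested, and the deviations of the 2 arrays correlated at 0.295 with each other.

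CDDO-Me and DMF changed overlapping genes, and a DMF response equal to the CDDO-Me response times one factor was tested. With 12 arrays limma found 0 genes departing at factors of 0.55 to 0.85, which cannot tell, as the same fit found few 2-fold changes in simulated data. With 10 arrays at least 353 genes departed at each factor tried from 0 to 1 in steps of 0.05, 214 above and 139 below at 0.75. No single factor in that range therefore described the log2 signals in that fit. The fit had no replicate block, and signals near the floor or the ceiling of the arrays could depart as well. Padi1 (1.54), Synpo (1.3) and Fos (1.22) lay above the scaled response and Hmox1 (-1.42), Edn2 (-1.19), Slc40a1 (-1.09) and Irs2 (-0.89) below it. For CDDO-Im as a multiple of CDDO-Me the smallest counts were 0 with 12 arrays (factors of 0.8 to 1.45, cannot tell) and 18 with 10 arrays. There too no single factor, from 0.5 to 1.5, described the log2 signals, with the same limits.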
